A study of Homo sapiens with 6 samples.

How the data were processed

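Total RNA of MDA-MB-231 cells was collected 48 h after transfection with pcDNA3.1 or pcDNA3.1-NFIC1 by a cationic lipid reagent, and 1 ug of it entered a directional (strand-marking) library kit, per the labels' protocols. There were 6 libraries, 3 in each of 2 groups, and the groups and replicate numbers were taken from the labels. The values in the deposited tables are FPKM, fragment numbers scaled to transcript length and library size, computed by the authors, per the file headers. The submitters' processing notes name DESeq 1.10.1 without saying what it was used for. The aligner, the quantification tool, the genome build, the annotation and whether quantification used strand are not given in the sources used here. The tables list 19974 Ensembl gene identifiers and 5997 loci that the authors assembled themselves. Symbols of 19413 identifiers came from a table of gene names and of the other 561 from GENCODE release 29, which also gave the coordinates printed (assembly GRCh38).

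FPKM are not counts, so no count model was used. The design fixed before the data were examined named a count model for counts, with limma for normalized values, and the latter applied. FPKM were converted to log2(FPKM + 1), and features with at least 1 FPKM in at least 3 libraries were tested (12062, of which 897 were assembled loci). The model compared the 2 groups with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend and robust settings, two-sided), with no block for replicate number. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Levels are given as mean ± SD over 3 libraries, and errors of log2 fold changes are limma standard errors. FPKM divides by the library total, so a change of total RNA per cell is not visible.

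Of 36 gene lists fixed in advance (838 genes, 825 found in the tables), 31 had at least 5 tested members. They were tested with camera from limma at a preset correlation between genes of 0.01, with an estimated correlation beside it, and with fry, each adjusted over the 31 lists. The estimated setting of camera takes its p from the few residual degrees of freedom that the libraries leave. The preset setting takes it from the number of genes, so a call lost between them need not come from correlation. Members past the threshold were counted after adjustment over all tested features and over the list alone. The genes named were NFIC and S100A2, the 12 largest log2 fold changes in each direction, and up to 4 members with the smallest p in each list. The 12 were taken among genes with an adjusted p under 0.05, no overlap between the groups, a symbol and a mean of at least 1 FPKM in the higher group. Others are named with the words that they were chosen after their values were seen.

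Depth is not stated with FPKM. It was estimated among 2776 genes with 1 annotated transcript, some of whose lowest values lie near whole multiples of what a fragment is worth. The step was sought only between 0.025 and 0.065 (FPKM times kb). In each library 26 to 43 genes lay at the step, and 8 to 14 in windows of equal width beside it. The estimates ran from 20.5 to 26.5 M (mega) fragments. These are estimates, and no count-based interval was derived from them. No pair of libraries had identical values above 0. The fit was tested on simulated data made from the means and spreads of this comparison (NFIC1 against control, 11971 genes tested). It called 91% of genes changed 2-fold and 65% of those changed 1.5-fold, 6.59% of its calls were unchanged genes, and none had the wrong sign. In a simulation over 12062 features, with 1 list shifted by 0.3, camera called that list and no other. Noise was drawn there for each gene on its own. The simulation therefore does not show how often camera calls unchanged lists whose genes vary together.

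Alternatives were other scalings of the libraries (median-of-ratios, upper-quartile, equal totals, and leaving out mitochondrial and ribosomal protein genes), no filter on low values, a pseudocount of 0.1, a block for replicate number and leaving out each library in turn. A minimum of 5 FPKM, leaving out the assembled loci and a fit without robust settings were added after the data were seen. Tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures with matplotlib 3.10.9.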

Results

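The series profiled total RNA of MDA-MB-231, a human triple-negative breast cancer cell line, 48 h after transient transfection. Control cells received an empty pcDNA3.1 plasmid (n = 3 libraries). NFIC1 cells received the same plasmid carrying NFIC1, a form of the transcription factor nuclear factor I C (n = 3 libraries). Expression was given as FPKM for 25971 features, and the sum over features lay between 406749 and 412790 FPKM per library. A step in the lowest values, shared by 26 to 43 genes per library among 2776 with a single annotated transcript, gave an estimate of the depth. It was about 20.5, 23.3 and 25.9 M (mega) fragments in control libraries 1 to 3. In NFIC1 libraries 1 to 3 it was about 21.9, 26.5 and 24.8 M fragments. The standard deviation of the log2 difference between libraries was 0.18 to 0.20 within a group and 0.20 to 0.22 across groups. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples. That spread may be technical.

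The first question was whether the transfected factor and S100A2, the gene named in the series title, differed between the groups. NFIC (ENSG00000141905) lies on chromosome 19, 3314403 to 3469217, on the plus strand in GENCODE release 29. It rose from 44.9 ± 8.93 FPKM in control to 2264 ± 356.5 FPKM in NFIC1 libraries (mean ± SD, n = 3 each). This was a log2 fold change of 5.63 (SE 0.19, limma adjusted p = 6.84e-04, and 0.072 with a block for replicate number). The 3 control libraries lay at 41.8, 37.9 and 54.9 FPKM and the 3 NFIC1 libraries at 2652, 2188 and 1951 FPKM, so every library matched its label. S100A2 (ENSG00000196754, chromosome 1, 153561108 to 153567890 on the minus strand) encodes a calcium-binding protein of the S100 family. It rose from 24.1 ± 0.94 to 41.9 ± 2.14 FPKM (log2 fold change 0.77, SE 0.05, limma adjusted p = 6.83e-05, n = 3 each). The other tested members of the NFI family did not pass the test. They had log2 fold changes of -0.13 (SE 0.09) for NFIA, 0.01 (SE 0.07) for NFIB and -0.10 (SE 0.06) for NFIX. Of the 9 tested S100 genes, S100A2 alone was past the threshold over all genes and also when adjusted over the list alone. S100A3 (0.15, SE 0.08) and S100A11 (0.05, SE 0.03) did not pass. The other 8 tested S100 genes had a median log2 fold change of 0.035 (SD 0.074), against 0.77 for S100A2. The S100 list, which includes S100A2, was past the threshold upward (camera adjusted p = 0.0369), with an adjusted p = 0.299 with an estimated correlation. With the preset one the call ended without control replicate 1 (0.108), NFIC1 replicate 1 (0.128) or NFIC1 replicate 3 (0.0851), and without a filter on low values (0.0768). FPKM values per gene do not tell plasmid transcripts from those of the chromosomal NFIC gene and do not resolve its isoforms.

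**Figure D1:**
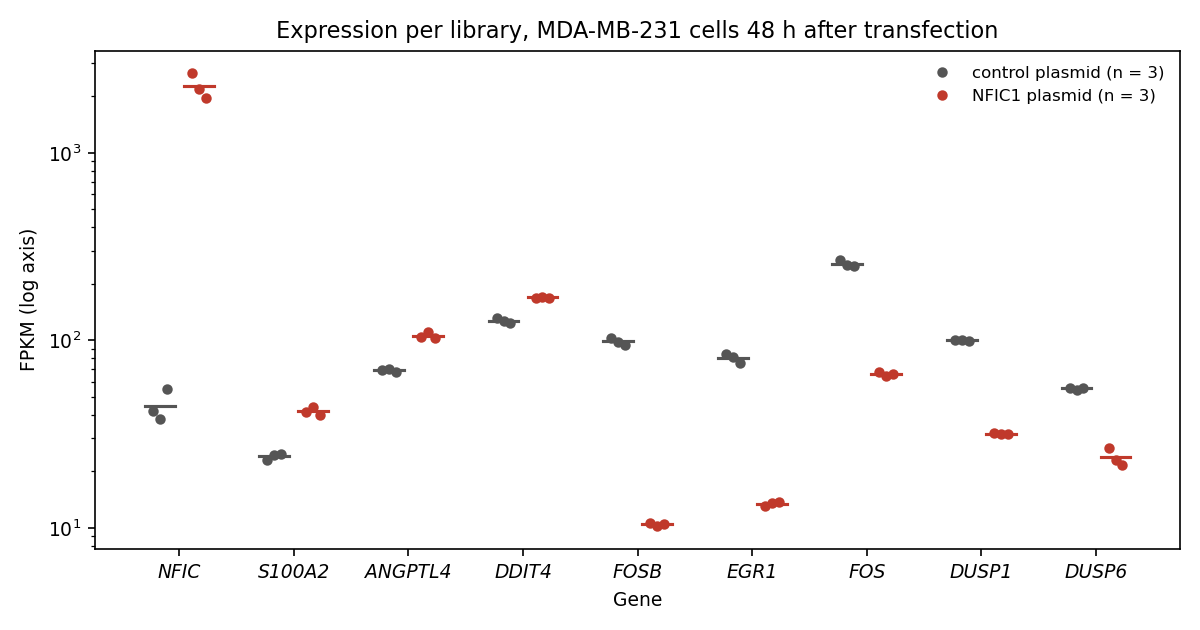
FPKM of 9 genes on a log axis in each of the 3 control (grey) and 3 NFIC1 (red) libraries; points are single libraries and horizontal bars are group means. NFIC rose from a mean of 44.9 to 2264 FPKM, S100A2 from 24.1 to 41.9 FPKM, and FOSB fell from 98.6 to 10.4 FPKM. The groups did not overlap for any gene shown, as the rule for the largest changes required.

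The second question was which genes changed with NFIC1. FOSB, which encodes a transcription factor of the AP-1 group, fell from 98.6 ± 4.12 to 10.4 ± 0.21 FPKM (log2 fold change -3.12, SE 0.04, n = 3 each, limma adjusted p = 1.26e-09). The transcription factor genes EGR1 and FOS fell from 80.4 ± 4.29 to 13.4 ± 0.37 FPKM (-2.49, SE 0.05) and from 255.2 ± 9.88 to 65.9 ± 1.45 FPKM (-1.94, SE 0.04). DUSP1, a phosphatase of MAP kinases, fell from 100.1 ± 0.67 to 31.7 ± 0.14 FPKM (-1.63, SE 0.03). The kinase gene SGK1 (-1.29, SE 0.08), the ERK phosphatase gene DUSP6 (-1.19, SE 0.07) and IER2 (-1.17, SE 0.04) fell by over 2-fold. So did the transcription factor genes ATF3 (-1.13, SE 0.06) and KLF4 (-1.09, SE 0.04). The transcription factor gene JUN (-0.97, SE 0.03), the matricellular protein gene CCN2 (-0.94, SE 0.03) and SAT1 (-0.84, SE 0.04), which encodes a polyamine acetyltransferase, completed the 12 largest falls. Their limma adjusted p lay between 7.31e-05 and 1.26e-09. FOSB overlaps ERCC1 on the other strand. Whether the authors' quantification used strand is not stated, so its level is uncertain to that extent.

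The 12 largest rises on the log2(FPKM + 1) scale were led by NFIC and S100A2. ACKR3, a scavenging chemokine receptor, had a log2 fold change of 0.67 (SE 0.10), and FBXO2 one of 0.63 (SE 0.08). Both have low levels, and their ratios of mean FPKM, 1.99 and 1.78, were above that of S100A2 (1.74). The log2 fold change of ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 0.61 (SE 0.04). It was 0.56 (SE 0.09) for VASN, 0.55 (SE 0.09) for the carbonic anhydrase gene CA9 and 0.50 (SE 0.09) for ICAM5. TBC1D3L (0.43, SE 0.08), the carboxypeptidase gene CPA4 (0.41, SE 0.04), DDIT4 (0.41, SE 0.03), an inhibitor of mTORC1, and LTBP3 (0.40, SE 0.06), which binds latent TGF-beta, followed (n = 3 each). ANGPTL4 rose from 69.3 ± 1.27 to 105.9 ± 3.74 FPKM and DDIT4 from 127.4 ± 3.68 to 169.3 ± 1.32 FPKM (limma adjusted p = 4.50e-05 and 2.89e-04). FBXO2, VASN and CA9 each overlap a gene on the other strand, and TBC1D3L belongs to a family of near-identical copies, so these levels are uncertain. The limma calls of ACKR3, VASN, CA9, ICAM5, TBC1D3L and LTBP3 ended in several alternatives. In that order they were past the threshold in 10 of 16, 9 of 17, 10 of 17, 8 of 16, 4 of 16 and 11 of 17 of the refits that tested them. Their highest adjusted p in those refits were 0.120, 0.154, 0.166, 0.154, 0.151 and 0.106.

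In all, 116 of 12062 tested features changed (limma, Benjamini-Hochberg adjusted p under 0.05), 58 higher and 58 lower with NFIC1. With upper-quartile factors 70 were higher and 52 lower, and with equal library totals 47 and 61. Of the 116, 10 changed at least 2-fold on the log2(FPKM + 1) scale: NFIC upward and 9 genes downward. All 3 libraries of one group lay above all 3 of the other for each of the 116 features. Selection by the test largely brings this about, so it adds no support for them. Such separation held for 2513 of all tested features (20.8%, where chance gives 10%). The changed features included 9 loci that the authors assembled outside their gene annotation. The count moved by over 1.5 times without control replicates 1, 2 or 3 (70, 67 and 63 changed) and without NFIC1 replicates 2 or 3 (62 and 66). Without a filter on low values it was 49.

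The series title names the MEK/ERK pathway, the kinase cascade from RAS to ERK, so the genes whose transcription ERK activity drives were compared as a list. The MEK/ERK output list fell (camera adjusted p = 3.05e-07 over 31 lists, median log2 fold change -0.08, mean -0.31). This call was lost with an adjusted p = 0.0849 with an estimated correlation. Of its 23 tested members 5 fell, none rose and 18 did not pass. When adjusted over the list alone, 9 fell. The 5 were EGR1, FOS, DUSP6, DUSP5 and SPRY2. Without them the other 18 had a median of -0.057 (camera p = 0.0218, and 0.0681 with an estimated correlation, both unadjusted). That test was chosen after the results were seen. DUSP5, an ERK phosphatase gene, fell from 36.1 to 28.8 FPKM (log2 fold change -0.32, SE 0.04). SPRY2, a feedback inhibitor of the pathway, fell from 14.2 to 10.7 FPKM (-0.38, SE 0.06) and was named after its values were seen; its limma call held in 9 of 17 refits. The limma call of DUSP5 ended without a filter on low values (adjusted p = 0.0571). None of the 20 tested components of the cascade itself passed the test. Among them were NRAS (-0.10, SE 0.04), MAP2K1 (0.07, SE 0.04) and RPS6KA1 (0.14, SE 0.05). That list did not pass either (camera adjusted p = 0.629).

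Of the 31 lists with at least 5 tested members, fixed before the data were examined, 16 were past the threshold with camera's preset correlation. With an estimated one 0 were in the main fit, and 10 had an unadjusted p under 0.05. By fry, which asks whether a list's genes move on balance one way, 13 lists were past the threshold. Cholesterol synthesis (downward, fry adjusted p = 0.00841) was added. The mitochondrially encoded mRNAs (0.111), type I interferon response (0.111), NF-kB inflammatory genes (0.0549) and cytosolic ribosomal proteins (0.522) were not past it.

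The hypoxia and glycolysis list had the lowest camera adjusted p (4.22e-15, median log2 fold change 0.14) and rose. With an estimated correlation it had an adjusted p = 0.0849 in the main fit. That p was 0.0226 with median-of-ratios factors, 0.0214 with upper-quartile factors and 0.0287 without mitochondrial and ribosomal protein genes. Of its 29 tested members 9 rose, none fell and 20 did not pass. The count adjusted over the list alone was 18 higher and 1 lower. Besides ANGPTL4 and CA9, NDRG1 rose from 383.2 to 498.3 FPKM (log2 fold change 0.38, SE 0.03). The glucose transporter gene SLC2A1 rose from 155.7 to 185.7 FPKM (0.25, SE 0.03) and the collagen prolyl hydroxylase gene P4HA1 from 40.5 to 50.1 FPKM (0.30, SE 0.04). The limma call of P4HA1 ended without a filter on low values (adjusted p = 0.0675, and 0.0562 with a pseudocount of 0.1).

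The extracellular proteases and inhibitors rose (camera adjusted p = 3.44e-07, and adjusted p = 0.109 with an estimated correlation). Of 14 members 1 was past the threshold, the metalloprotease gene ADAM8 (63.8 to 83.7 FPKM, 0.39, SE 0.04). There were 7 higher when adjusted over the list alone. CTSL (0.15, SE 0.04), CTSB (0.27, SE 0.07) and TIMP1 (0.15, SE 0.04) did not pass. The epithelial markers rose (camera adjusted p = 4.31e-04, and adjusted p = 0.134 with an estimated correlation). The tight-junction gene CLDN7 (0.34, SE 0.06) was the 1 of 14 past the threshold, and 4 were higher when adjusted over the list alone. The median of 0.113 was 0.045 without a filter on low values and 0.072 with the minimum of 5 FPKM added after the data were seen. CLDN7 overlaps another gene, and its limma call ended without each of the 6 libraries in turn. The mesenchymal markers were past the threshold upward (camera adjusted p = 0.0473, and adjusted p = 0.309 with an estimated correlation). LOX, a collagen cross-linking enzyme (18.3 to 23.5 FPKM, 0.35, SE 0.04), was the 1 of 17 past the threshold; it overlaps a gene on the other strand. There were 5 higher when adjusted over the list alone. That list's call ended without control replicate 2 (0.246), control replicate 3 (0.0709), NFIC1 replicate 1 (0.118) or NFIC1 replicate 2 (0.0708). It also ended with the block for replicate number, with equal library totals (0.0572) and without a filter on low values (0.225), where the median turned to -0.001. In all it held in 9 of 17 refits, with a highest camera adjusted p of 0.256. The integrin and focal adhesion list (0 of 23 members) and the actin and motility list (1 of 26) did not pass (camera adjusted p = 0.306 and 0.313). The 1 member was RHOB, a small GTPase gene (-0.45, SE 0.04). Adjusted over the list alone, 1 integrin list gene was higher and 1 actin list gene lower. The basal keratin list (0 of 5, camera adjusted p = 0.687) and the luminal breast markers (0 of 6, 0.714) did not pass. Adjusted over the list alone, 1 basal keratin list gene was higher and 1 lower.

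**Figure D2:**
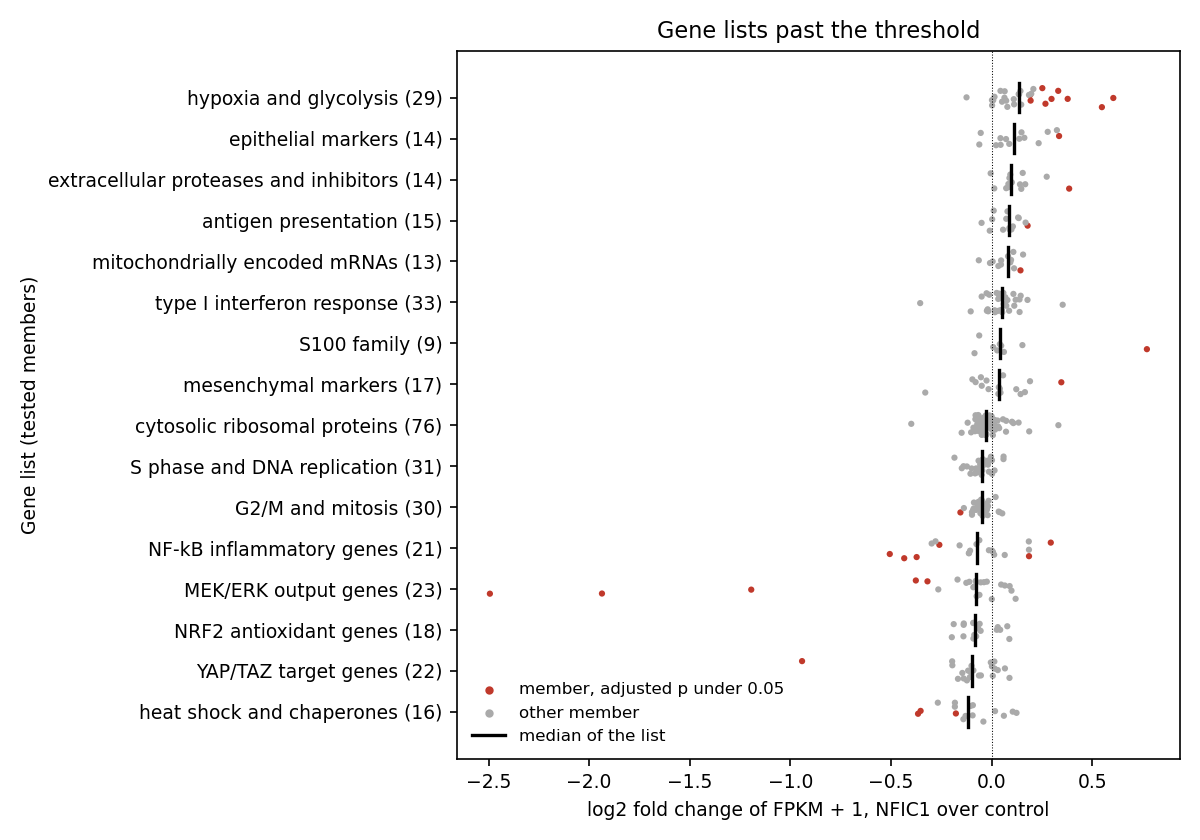
The log2 fold change (NFIC1 over control, FPKM + 1) of each tested member of the 16 gene lists past the threshold with camera's preset correlation, with the number of tested members in parentheses. Red points are members with a limma adjusted p under 0.05, grey points the others, and black bars list medians. The medians ran from -0.12 for heat shock and chaperones to 0.14 for hypoxia and glycolysis.

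Stress, growth and inflammatory lists included several that fell. Heat shock genes and chaperones fell (camera adjusted p = 8.39e-06, and adjusted p = 0.0849 with an estimated correlation). Of 16 members 3 fell, and adjusted over the list alone 10 were lower and 1 higher. The 3 that fell over all genes were HSPA1A (-0.37, SE 0.04), HSPA1B (-0.35, SE 0.03) and HSP90AA1 (-0.18, SE 0.03). HSPA1A and HSPA1B are near-identical copies, so their separate levels are uncertain, and HSP90AA1 overlaps a gene on the other strand. YAP/TAZ target genes fell (camera adjusted p = 1.25e-04, and adjusted p = 0.0849 with an estimated correlation). CCN2 was the 1 of 22 past the threshold, and 8 were lower when adjusted over the list alone. The G2/M list (CDC20 lower, 1 of 30, -0.15, SE 0.03), the S phase list (0 of 31) and the NRF2 antioxidant list (0 of 18) fell by medians of -0.05, -0.05 and -0.08 (camera adjusted p = 0.00143, 0.00372 and 0.0021). These lists had an adjusted p = 0.134, 0.134 and 0.137 with an estimated correlation. Adjusted over the list alone, 1, 0 and 5 members were lower. NF-kB inflammatory genes moved both ways. Of 21 tested members the cytokine genes CXCL8 (-0.37, SE 0.03) and CXCL2 (-0.51, SE 0.06), NFKBIZ (-0.43, SE 0.06) and CSF2 (-0.26, SE 0.04) fell. CXCL1 (0.29, SE 0.04) and TNFAIP2 (0.19, SE 0.03) rose. CSF2 and TNFAIP2 were named after their values were seen, and their limma calls held in 8 and 6 of 17 refits. Adjusted over the list alone 6 fell and 3 rose. The list was past the threshold downward (camera adjusted p = 0.0369, and adjusted p = 0.398 with an estimated correlation). Its call ended without control replicate 1 (0.114) or NFIC1 replicate 3 (0.071), with a minimum of 5 FPKM (0.145, added after the data were seen) and without a filter on low values (0.110, median -0.013). Without that filter the limma call of NFKBIZ also ended (adjusted p = 0.0824). The limma call of CDC20 ended without each library in turn and with upper-quartile factors (0.0603), and that of HSP90AA1 without each but NFIC1 replicate 1.

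Antigen presentation genes rose (camera adjusted p = 3.71e-04, and adjusted p = 0.0849 with an estimated correlation). HLA-B (257.0 to 291.2 FPKM, 0.18, SE 0.03) was the 1 of 15 past the threshold, and 4 were higher when adjusted over the list alone. HLA genes resemble each other and can share reads, and HLA-B and HLA-C overlap, so their levels are uncertain. The limma call of HLA-B ended without each library in turn. The list of 13 mitochondrially encoded mRNAs was past the threshold upward (camera adjusted p = 3.71e-04, and adjusted p = 0.309 with an estimated correlation). MT-CO1 was the 1 of 13 past the threshold (0.14, SE 0.02), 11 had a log2 fold change above 0 and 2 below, and 5 were higher when adjusted over the list alone. The share of mitochondrial genes in all FPKM was at most 15.3% in control and at least 15.5% in NFIC1 libraries. The call of the list ended without a filter on low values (0.0617), and its median of 0.082 was 0.038 without control replicate 2. The limma call of MT-CO1 ended without control replicates 2 or 3 or NFIC1 replicates 1 or 2. The type I interferon response list was past the threshold upward (camera adjusted p = 0.0146, and adjusted p = 0.257 with an estimated correlation). It had 0 of 33 members past the threshold and 1 when adjusted over the list alone. Its call ended without NFIC1 replicate 1 (0.0705), where the median of 0.051 was 0.019. Cytosolic ribosomal protein genes (0 of 76) were past the threshold downward by a median of -0.03 (camera adjusted p = 0.0473, and adjusted p = 0.652 with an estimated correlation). That call ended without control replicates 2 or 3 (0.115 and 0.5) or NFIC1 replicates 1 or 2 (0.401 and 0.3). It also ended with upper-quartile factors (0.147) and with the added minimum of 5 FPKM (0.143) or leaving out the assembled loci (0.0584). The median of -0.027 was -0.014 without control replicate 3 or NFIC1 replicate 2, -0.015 with upper-quartile factors and -0.044 without NFIC1 replicate 3.

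Some of the lists that did not pass still held changed genes. Of 21 TGF-beta response genes LTBP3 was higher and CCN2 and ID1 (-0.31) were lower (camera adjusted p = 0.103). Of 25 genes of the ATF4 and amino acid response DDIT4 was higher and ATF3 lower (0.517). Of 20 p53 targets GADD45A (-0.29) was lower (0.813). The limma call of ID1 ended without each library in turn and with median-of-ratios or upper-quartile factors (0.056 and 0.0648), and that of GADD45A without each but NFIC1 replicate 2. Replication-dependent histones (0 of 12 members, camera adjusted p = 0.0743), the unfolded protein response (0 of 20, 0.117), leukocyte markers (0 of 5, 0.156) and cholesterol synthesis (0 of 23, 0.188) did not pass. Nor did metallothioneins (0 of 6, 0.549), fatty acid synthesis (0 of 15, 0.615) and nuclear oxidative phosphorylation genes (0 of 63, 0.813). The histone list was past the threshold downward in 4 of 16 refits. These were without control replicate 1 (0.0176), control replicate 3 (0.0330) or NFIC1 replicate 2 (0.0297), and with the block for replicate number. The TGF-beta list was past it upward without NFIC1 replicate 1 (0.0314). Outside that histone list, the histone genes H2BC21 (-0.73, SE 0.08), HIST2H2AA3 (-0.61, SE 0.08) and HIST2H2AA4 (-0.60, SE 0.07) fell, and were named after their values were seen. The last pair are near-identical copies, so their separate levels are uncertain, and their limma calls ended without a filter on low values (0.0778 for each). Adjusted over the list alone, 1 histone gene and 1 cholesterol gene were lower. On that basis 5 TGF-beta genes were higher and 2 lower, 1 gene of the ATF4 response was higher and 4 lower, and 2 p53 targets were higher and 2 lower. The median and the mean of the basal keratin list (0.02 and -0.004) and of the oxidative phosphorylation list (0.003 and -0.001) differed in sign. Of the lists with fewer than 5 tested members, the interferon genes and antiviral chemokines had 1 tested member, TNFSF10. It encodes the death ligand TRAIL and rose from 42.4 to 55.7 FPKM (0.39, SE 0.04). None of the 4 fibroblast and 2 endothelial markers tested passed, and no nuclear-retained RNA of the fixed list was tested.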

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

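The stricter minimum, leaving out assembled loci and the fit without robust settings were chosen after the data were seen, the others before. In these 17 refits none of the 116 calls changed sign. The count of 116 changed features (58 higher, 58 lower) fell to 49 (20 higher, 29 lower) without a filter on low values and to 52 (21 and 31) with a pseudocount of 0.1 and no filter, where 22354 features were tested. Leaving out 1 library gave 62 to 82 changed features, 23 to 32 higher and 35 to 50 lower, from fewer samples. The counts were 70, 67 and 63 without control replicates 1, 2 and 3, and 82, 62 and 66 without NFIC1 replicates 1, 2 and 3. The labels do not say whether the replicate numbers pair the libraries. Same-numbered libraries of the 2 groups had correlations of -0.007, 0.066 and 0.016 of their deviations, and differently numbered ones -0.058 to 0.043. Values so near 0 do not decide whether the libraries were paired by design. The replicate block gave 57 changed features (24 higher, 33 lower, 54 shared with the unblocked fit). NFIC had the same log2 fold change of 5.63 with a limma adjusted p = 0.072 (range over its refits 4.30e-07 to 0.072). The block leaves fewer residual degrees of freedom, and how much of the higher p this accounts for was not tested. Counts of genes changed at least 2-fold stayed between 9 and 12. S100A2 was past the threshold in all 17 refits, with log2 fold changes of 0.73 to 0.80. Of the 43 other genes past the threshold named by the rule, 27 were so in every refit that tested them and 16 were not; of the 22 named after their values were seen, 8 were and 14 were not. Of the 16 lists past the threshold, 10 were so in every refit. With an estimated correlation 0 lists passed in the main fit, the lowest camera adjusted p being 0.0849. The hypoxia and glycolysis list did pass under 3 of the 4 scalings. The MEK/ERK output list (median -0.079) was among those lost in the main fit. Its estimated correlation, 0.022, was above the preset one, but the estimated setting also uses far fewer degrees of freedom. How much of the loss came from each was not tested. For the YAP/TAZ and antigen presentation lists, also lost, a higher correlation between genes was not the cause. Their estimated correlations, 0.006 and -0.054, were below the preset 0.01. The median of the MEK/ERK output list ran from -0.098 to -0.058 over the refits, all past the threshold. Without a filter on low values, with either pseudocount, the calls of P4HA1, NFKBIZ, CLDN7, ID1, HLA-B, HSP90AA1, GADD45A, CDC20 and MT-CO1 ended, as did those of the mesenchymal, NF-kB, S100 and mitochondrial mRNA lists. DESeq2 and limma-voom were not run because they need counts, and a minimum in CPM was replaced by the FPKM minimum. Depth sets no exact limit here, since it was only estimated.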

Other observations

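The genes in the following 2 paragraphs were chosen after the results were seen. So were the tests in this part, apart from the count of splits for all changed genes. The tests of the heat shock, ATF4 and hypoxia lists were planned, and their use in this part was chosen afterwards. Immediate-early genes are those that cells induce soon after a stimulus without new protein synthesis. Of 42 such genes 35 were tested, and 22 were lower with NFIC1 and 0 higher (limma). The share of all tested features that were lower would give 0.168 (two-sided Fisher's exact test, p = 1.48e-44). Because this list was written with the falling genes in view, that p and the count of 0 higher describe it and are not independent evidence. CXCL1 and ERRFI1, which rose (0.29 and 0.27), were not on it, and another choice of genes could hold some that rose. Beyond the 9 genes lower by at least 2-fold, 14 of 27 were lower, among them JUNB (73.7 to 41.9 FPKM, log2 fold change -0.80, SE 0.04), KLF6 (80.9 to 49.0 FPKM, -0.71, SE 0.03), MCL1 (-0.55, SE 0.04) and ZFP36 (-0.56). FOSL2 (0.002, SE 0.04) and FOSL1 (-0.06, SE 0.03) did not pass. Members of the MEK/ERK output list also parted. Beside the fall of DUSP6 and EGR1, DUSP4 (-0.02, SE 0.05), ETV4 (0.05, SE 0.05), ETV5 (-0.04, SE 0.05) and SPRY4 (-0.05, SE 0.05) did not pass. ERRFI1, which is not on that list and encodes an inhibitor of the EGF receptor, rose from 114.7 to 138.4 FPKM (0.27, SE 0.03).

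Of genes of polyamine metabolism, SAT1 (-0.84, SE 0.04) and ODC1, the first enzyme of polyamine synthesis (-0.35, SE 0.04), fell. SMS (0.02, SE 0.03), AMD1 (-0.03, SE 0.06) and OAZ1 (0.00, SE 0.03) did not pass. The lipid droplet genes PLIN2 (202.4 to 252.8 FPKM, 0.32, SE 0.03) and HILPDA (0.31, SE 0.04) rose, as did LCN2 (0.30, SE 0.04) and the complement genes C3 (0.25, SE 0.03) and CFB (0.30, SE 0.05). The cyclin L genes went opposite ways, CCNL1 at -0.48 (SE 0.05) and CCNL2 at 0.32 (SE 0.06). MST1R, a receptor kinase, rose (0.38, SE 0.07), as did SPINT1 (0.36, SE 0.07) and SPINT2 (0.20, SE 0.03), which encode inhibitors of serine proteases that activate its ligand. Several calls ended in some of the 17 refits. The number of refits past the threshold was 16 for ODC1, 14 for C3, 11 for ZFP36 and LCN2, 9 for CFB and SPINT2, 8 for MST1R, 7 for CCNL2 and 6 for SPINT1. No list of these genes was tested for enrichment.

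The 6 libraries allow 10 splits into 3 and 3, so the share of splits as extreme as the real one cannot go below 0.1. Every other split mixes libraries of the 2 groups, so a real group difference adds to the spread within each side. Low counts of changed features there are thus largely fixed in advance and are not a rate of false calls. The real split gave 116 changed features and the highest other split 5, so 1 split, the real one, reached that value. The same count of 1 held for features higher (58, highest other 4) and lower (58, highest other 4). For the other splits, whose direction is arbitrary, the larger of the counts higher and lower was taken. It also held for features changed at least 2-fold (10, highest other 4) and lists past the threshold (16, highest other 5). The other splits put 4, 5, 1, 0, 1, 2, 4, 1 and 3 lists past the threshold. Camera with the preset correlation therefore also called lists when the groups were mixed, which limits the weight of the 16.

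The fall of 9 genes by at least 2-fold had a median log2 fold change of -1.29. The values argue against library scaling as its cause, since the median of all tested features was -0.005. The median of the 9 genes nearest to 0 over 4 scalings was -1.28. Those refits were weak tests, since the median-of-ratios, upper-quartile and total factors lay between 0.986 and 1.012. Lower MEK/ERK output stays open: without the 5 genes past the threshold, the other 18 tested members of that list had a median of -0.057 (camera p = 0.0218, and p = 0.0681 with an estimated correlation, both unadjusted). A different handling or harvest of the groups stays open as well, since the heat shock list, which responds to handling stress, also fell (median -0.117, camera p = 1.08e-06, and 0.0108 with an estimated correlation, both unadjusted). Immediate-early genes may respond to either, and the labels do not say how the dishes were harvested, so an effect of NFIC1 is a hypothesis.

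For the rise of the hypoxia and glycolysis list, the values argue against library scaling as the cause. The list's median was 0.137 and that of all tested features -0.005. Its lowest median over the 4 scalings was 0.126, with a camera adjusted p of at most 1.14e-14. Those refits were weak tests, since the factors were near 1 and camera compares a list with the other genes. With an estimated correlation the list was not past the threshold with equal library totals. Denser or more depleted cultures could raise such genes too; the ATF4 and amino acid response list, which nutrient loss raises, had a median of -0.039 (camera adjusted p = 0.517; over the refits -0.050 to -0.007, none past the threshold), which decides neither way. The YAP/TAZ, G2/M and S phase lists, which can fall in dense cultures, fell (camera adjusted p = 1.25e-04, 0.00143 and 0.00372). With an estimated correlation none of these was past the threshold (camera adjusted p = 0.0849, 0.134 and 0.134). These lists were weighed after their values were seen, and the explanation stays open. The labels record no difference in culture between the groups; one that went with the groups could not be told apart from NFIC1 here.

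The rise of S100A2 by 0.77 was not shared by its neighbours. A shift of the whole S100 cluster would raise the other 8 tested S100 genes, all on chromosome 1, and their median was 0.035 (SD 0.074). A direct effect of NFIC1 on S100A2 was not tested.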
